A study of Mus musculus with 30 samples.

How the data were processed

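According to the submitters' processing notes, ovaries were flash frozen, RNA was prepared with RNeasy columns, and stranded TruSeq mRNA libraries were sequenced as single reads on an Illumina HiSeq instrument. The same notes name FastQC 0.11.8, Salmon 0.11.3, edgeR without a version, and R 3.5.2, with transcripts of GRCm38.p6. The authors deposited 1 table of log2 CPM with 18022 genes and 30 columns, which was used as it stands. Its lowest value was -3.343 log2 CPM (0.0986 CPM), and back-transformed column sums ran from 907668 to 1164842. Whole read counts could not be recovered from it, so depth was approximated from the smallest steps between values, and count-based tests were not used here. Of the Entrez identifiers 17770 (98.6%) were matched to the annotation table of the same build, and 15 genes had no symbol.

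Genes with a mean log2 CPM above 0 were kept, which left 14740. Each was fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 1 mean per group over all 30 libraries and a mean-dependent prior variance. Residual degrees of freedom were 20, the prior added 2.85, and the median residual SD was 0.246 log2. Adjusted p-values are Benjamini-Hochberg within each comparison, and a gene passed under 0.05. Libraries of the same group correlated at r = 0.908 to 0.98. Principal component 1 held 28.1% of the variance.

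Of 32 gene lists fixed beforehand, 27 with at least 5 genes after the filter were tested with camera at the preset correlation of 0.01, with camera at an estimated correlation, and with fry. The 9 comparisons tested first were the 8 of treated groups with controls and that of controls over time. They were adjusted together, and the 10 compound, dose and time-by-treatment comparisons, added after the data were seen, were adjusted together apart from these. Not tested were the T, B and NK cell (2 genes), erythrocyte (4), skeletal muscle (2), exocrine pancreas (2) and mitochondrially encoded (0) lists. List members were also adjusted over their list alone.

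Genes were named by a rule written before the data were examined. It takes the 3 smallest p in each direction for each treated-versus-control comparison, the smallest p for each other comparison, and a panel of 16 reproductive genes. The panel comprises Star, Cyp11a1, Hsd3b1, Cyp17a1, Cyp19a1, Hsd17b1, Fshr, Lhcgr, Esr1, Esr2, Amh, Inha, Inhba, Gdf9, Bmp15 and Kitl. Members of gene lists are given as examples beside their list. Values of a few single genes are not reported here.

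Simulated data had the same variances and 50 changed genes at each fold, all folds at once. Over the 8 treated-versus-control comparisons 20 to 42% of changes of 1.5-fold, 58 to 74% of 2-fold, 84 to 94% of 4-fold and 94 to 100% of 8-fold were recovered, with 3 to 18 unchanged genes called. For the lists, a shift of 0.6 in the oocyte list was called with 0 of 215 unshifted tests. A shift of 0.3, simulated first, was not called. With no change but members of a list correlated at 0.5, the preset correlation called 84 of 216 tests and the estimated correlation 0 of 216.

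The alternatives were median centring, quantile normalization, no filter, a stricter filter of mean log2 CPM above 2, an added pseudocount of 1 CPM, fits without the trend, robust fits and array weights. Others were fits of each time point or each comparison alone, replicate number as a block, list means as covariates, a 1.5-fold minimum, adjusted p under 0.10, adjustment over 8 comparisons together, and leaving out each library. The block columns were first coded against replicate 1, so that the time comparisons used replicate 1 only, and were recoded to sum to 0 within each time point before any value was reported. Fold changes of the 4 treatments were correlated in pairs and compared with 100 simulated draws that share controls and have no effect. Group labels were exchanged in all 10 splits of 3 against 3, or in 100 random regroupings that include the real one. Alternative splicing, single-cell references and pathway databases were not used here.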

Results

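Messenger RNA of whole ovaries from adult female CD1 mice, an outbred stock, was sequenced in 30 libraries that form 10 groups of 3. For 10 days the mice were given a vehicle, di(2-ethylhexyl) phthalate (DEHP) at 20 or 200 ug/kg/day, or diisononyl phthalate (DiNP) at 20 or 100 ug/kg/day. Both compounds are plasticizers of polyvinyl chloride, and DiNP serves as a replacement for DEHP. Ovaries were taken directly after dosing (0 months) or 3 months later, so that each time point has 4 treated groups and 1 control group. The deposited table gives log2 CPM (counts scaled to a common library depth) for 18022 genes and no read counts. The smallest steps between its values correspond to approximately 24.6 to 40.8 M reads per library (M, mega), with a median of 29.95 M.

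In the order of replicates 1 to 3, the approximate depths at 0 months were 30, 29.8 and 29.5 M reads in controls. They were 30, 31.6 and 32.5 M with DEHP 20, and 30.8, 24.6 and 40.8 M with DEHP 200. DiNP 20 had 31.9, 29.9 and 30.1 M, and DiNP 100 had 31.1, 34.5 and 31.3 M. At 3 months the depths were 34.2, 29 and 25.8 M in controls. The DEHP 20 libraries had 28.6, 31 and 28.4 M and the DEHP 200 libraries 28.5, 36.9 and 27.5 M. The DiNP 20 libraries had 24.7, 33.2 and 29.9 M and the DiNP 100 libraries 25.1, 27.3 and 25.6 M.

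Steroidogenic genes were among the abundant transcripts of control ovaries at 0 months. Cyp11a1 (Entrez 13070), which encodes the enzyme that cleaves the cholesterol side chain, stood at 12.57 ± 0.33 log2 CPM (SD, n = 3). Hsd3b1 (Entrez 15492) stood at 12.32 ± 0.27 and Star (Entrez 20845), the mitochondrial cholesterol carrier, at 10.05 ± 0.65. Changes below are log2 fold changes of group means with 3 libraries in each group, ± is the standard error for a fold change and the SD for a group mean, and coordinates are those of GRCm38.p6. Genes were tested with limma (14740 genes), gene lists with camera, and both adjusted p-values by Benjamini-Hochberg. The labels do not say that the replicates are separate mice, so that the p-values measure only the spread between these samples. A list called "higher" or "lower" passed camera with the preset correlation of 0.01 at an adjusted p under 0.05. Of 243 list tests 65 passed, 33 of them higher and 32 lower, and 0 of the 65 held with an estimated correlation, where the lowest adjusted p was 0.289. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 0 lists, with a lowest adjusted p of 0.826. Its version for changes in either direction, which makes no such comparison either, also called 0.

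At 0 months the first question was what 10 days of DEHP at 20 ug/kg/day did to the ovary. Interferon response genes were higher in 21 of 22 members, with a median of 0.81 (adjusted p = 1.35e-18; adjusted p = 0.64 with an estimated correlation). Rtp4 differed by 1.11 ± 0.35, Isg15 by 1.53 ± 0.55 and Oas1a, an antiviral oligoadenylate synthetase, by 1.62 ± 0.58, while Gbp2 was at -0.14. Unfolded protein response genes were lower in 21 of 21 members, with a median of -0.43 (adjusted p = 5.61e-12; adjusted p = 0.64 with an estimated correlation). Among them were the chaperone genes Hsp90b1 (-0.70 ± 0.28) and Dnajb9 (-0.45 ± 0.14). Ovarian surface and mesothelium genes were lower in 11 of 13 members, with a median of -0.49 (adjusted p = 5.05e-07; adjusted p = 0.445 with an estimated correlation). The keratin gene Krt7 (-0.92 ± 0.33) and the uroplakin gene Upk3b (-0.67 ± 0.26) were lower, and Krt8 (0.33) and Wt1 (0.19) were not. Of the members of these lists 0 passed when adjusted over the list alone, and 0 over all genes.

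In the same comparison 3 further calls each ended when single libraries were left out. The oocyte list was higher in 21 of 24 members (median 0.21, adjusted p = 0.0351; adjusted p = 0.987 with an estimated correlation), with Bmp15 at 0.38 ± 0.39 and Kit at -0.46 ± 0.40. That call ended without DEHP 20 replicate 2 (mean -0.01) or control replicate 2 (0.02). Proliferation genes were higher in 27 of 30 members (median 0.14, adjusted p = 0.00913; adjusted p = 0.987 with an estimated correlation), with Cdc20 at 0.38 ± 0.27, and the call ended without DEHP 20 replicate 1 (mean 0.04) or control replicate 3 (0.08). Immediate early and dissociation stress genes were lower in 14 of 21 members (median -0.39, adjusted p = 0.00392; adjusted p = 0.924 with an estimated correlation), with the heat shock gene Hspa1b at -2.02 ± 0.79 but Nr4a1 at 0.73. Without control replicate 3 this list's mean was -0.18 and it was not called.

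No single gene passed in DEHP 20 against control at 0 months, where limma called 0 genes and 350 had an unadjusted p under 0.05, against 737 expected by chance. The count was 175 without control replicate 2. Obox2 (Entrez 246792, chromosome 7, 15388851 to 15398545), of the oocyte-specific homeobox family, was the gene with the smallest p (3.73 ± 0.82, adjusted p = 1), at 3.35 ± 0.17 against -0.38 ± 2.74 log2 CPM. Its control SD came from replicates 1 and 2 at -2.19 and -1.72 and replicate 3 at 2.78. Without control replicate 3 Obox2 passed in all 4 treated groups at 0 months and made the count 1 in each. Of the others chosen by rank, Gtpbp10 differed by 0.40 ± 0.11, Mill2 by 1.39 ± 0.40, Zfp120 by -0.36 ± 0.09, Tm4sf5 by -1.29 ± 0.35 and Nrgn by -1.11 ± 0.32. The panel of 16 reproductive genes ranged from Cyp19a1 (aromatase) at -0.49 ± 0.85 to Kitl at 0.67 ± 0.75.

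DEHP at 200 ug/kg/day was compared with control at 0 months to see what the higher dose did. Extracellular matrix genes were lower in 24 of 28 members, with a median of -0.31 (adjusted p = 5.37e-07; adjusted p = 0.791 with an estimated correlation). The basement membrane collagens Col4a1 (-0.64 ± 0.22) and Col4a2 (-0.61 ± 0.22) and the laminin gene Lamc1 (-0.49 ± 0.18) were lower, and Postn (0.29) and Mmp2 (0.32) were not. Without DEHP 200 replicate 3 the list's mean went from -0.32 to -0.14 and it was still called. Genes of the unfolded protein response were lower in 21 of 21 members, with a median of -0.41 and Hyou1 at -0.67 ± 0.22 (adjusted p = 6.43e-09; adjusted p = 0.751 with an estimated correlation). Genes of the interferon response were higher in 21 of 22 members, with a median of 0.55, Oas1a at 1.65 ± 0.58 and Gbp2 at -0.18 (adjusted p = 1.54e-06; adjusted p = 0.916 with an estimated correlation). Immediate early and dissociation stress genes were lower in 21 of 21 members, with a median of -0.68 and Junb at -1.04 ± 0.46 (adjusted p = 0.000144; adjusted p = 0.791 with an estimated correlation). In each list 0 members passed when adjusted over the list alone.

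For DEHP 200 at 0 months 5 calls ended without single libraries. Ribosomal protein genes were higher in 30 of 30 members (median 0.14, adjusted p = 7.76e-05; adjusted p = 0.987 with an estimated correlation), with Rpl30 at 2.22 ± 0.97, and were not called without DEHP 200 replicate 3 (mean 0.13). Macrophage genes were higher in 18 of 19 members (median 0.30, adjusted p = 0.00478; adjusted p = 0.987 with an estimated correlation), with Aif1 at 0.56 ± 0.31 and Mrc1 at -0.18. That call ended without control replicate 1 (mean 0.20) or DEHP 200 replicate 2 (0.14). Oxidative phosphorylation genes were higher in 20 of 24 members (median 0.13, adjusted p = 0.0126; adjusted p = 0.987 with an estimated correlation), with Atp5o at 0.26 ± 0.17, but not without control replicate 2 (mean 0.08) or DEHP 200 replicate 2 (-0.08). PI3K signalling genes were lower in 16 of 22 members (median -0.12, adjusted p = 0.0225; adjusted p = 0.751 with an estimated correlation), with Foxo3, a brake on primordial follicle activation, at -0.27 ± 0.11 and Kitl at 0.92. They were not called without control replicate 3 (mean -0.08) or DEHP 200 replicate 2 (-0.02). Ovarian surface genes were lower in 12 of 13 members (median -0.37, adjusted p = 0.0208; adjusted p = 0.916 with an estimated correlation), with Lrrn4 at -0.98 ± 0.42, but not without control replicate 3 (mean -0.28), DEHP 200 replicate 1 (-0.31) or DEHP 200 replicate 2 (-0.29).

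With DEHP 200 at 0 months limma called 0 genes and 740 had an unadjusted p under 0.05. That number was 301 without control replicate 2, 1671 without DEHP 200 replicate 1 and 432 without DEHP 200 replicate 3. Gstz1 (Entrez 14874, chromosome 12, 87147161 to 87164723), an enzyme of tyrosine breakdown, was nearest to passing (0.49 ± 0.10, adjusted p = 0.411), at 5.59 ± 0.08 against 5.10 ± 0.12 log2 CPM. Obox2 differed by 3.35 ± 0.82, with the pair of near-absent control libraries, and the pseudogene Llph-ps2 by 1.60 ± 0.41. On the lower side were Tmf1 (-0.40 ± 0.10), Fndc3b (-0.66 ± 0.17) and Emp1 (-0.50 ± 0.14). The panel ranged from Cyp11a1 at -0.89 ± 0.75 to Kitl at 0.92 ± 0.75. Replicates 2 and 3 of this group stood apart in opposite directions, with corpus luteum list means of 9.98 and 6.19 log2 CPM against 8.89 ± 0.17 in controls. Their 10 highest genes held 9.9% and 10.1% of the column sum against 5.8 to 7.7% in the other libraries at 0 months. Replicate 2 had the lowest array weight at 0 months (0.237) and 159 genes at the lowest value of the table.

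DiNP at 20 ug/kg/day, compared with control at 0 months, asked what the replacement compound did at the dose it shares with DEHP. Granulosa cell genes were lower in 17 of 20 members, with a median of -0.43 (adjusted p = 0.000208; adjusted p = 0.874 with an estimated correlation). Nppc, whose peptide holds oocytes in meiotic arrest, differed by -0.83 ± 0.37 and Nap1l5 by -0.67 ± 0.29, while Amh (0.10), Foxl2 (0.15) and Slc18a2 (0.32) were not lower. The unfolded protein response list was lower in 18 of 21 members, with a median of -0.46, Sesn2 at -0.49 ± 0.19 and Chac1 at 0.67 (adjusted p = 3.14e-09; adjusted p = 0.751 with an estimated correlation). In both lists 0 members passed when adjusted over the list alone.

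The other 5 calls for DiNP 20 at 0 months ended without single libraries. The interferon response list was higher in 19 of 22 members (median 0.36, adjusted p = 0.000161; adjusted p = 0.987 with an estimated correlation), with Zbp1 at 1.79 ± 0.71 and Irf9 at -0.06, and not called without control replicate 3 (mean 0.28). Proliferation genes were lower in 30 of 30 members (median -0.17, adjusted p = 9.32e-05; adjusted p = 0.987 with an estimated correlation), with Ccnd2, the cyclin of granulosa cells, at -0.44 ± 0.21, but not without control replicate 1 (mean -0.11) or DiNP 20 replicate 1 (-0.05). Immediate early genes were lower in 18 of 21 members (median -0.32, adjusted p = 0.000847; adjusted p = 0.874 with an estimated correlation), with Dnajb1 at -0.83 ± 0.26 and Fos at 0.32, but not without DiNP 20 replicate 3 (mean -0.24). Endothelial genes were lower in 13 of 16 members (median -0.12, adjusted p = 0.0264; adjusted p = 0.987 with an estimated correlation), with Tie1 at -0.34 ± 0.18 and Kdr at 0.26. Their call ended without control replicate 2 (mean -0.08), control replicate 3 (-0.06), DiNP 20 replicate 2 (-0.13) or DiNP 20 replicate 3 (-0.09). Smooth muscle genes were lower in 10 of 11 members (median -0.20, adjusted p = 0.034; adjusted p = 0.987 with an estimated correlation), with Tagln at -0.39 ± 0.27. The call did not hold without control replicate 1 (mean -0.15), control replicate 2 (-0.09), DiNP 20 replicate 1 (-0.16) or DiNP 20 replicate 3 (-0.04).

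For DiNP 20 at 0 months limma called 0 genes and 307 had an unadjusted p under 0.05, or 650 without DiNP 20 replicate 3. Obox2 stood at 3.12 ± 0.32 log2 CPM, against the same control libraries, while Gtpbp10 differed by 0.42 ± 0.11 and Ddx52 by 0.23 ± 0.07 (each adjusted p = 1). Zfp607b was at -0.53 ± 0.12, Cuedc1 at -0.40 ± 0.11 and Fetub, a gene for a zona-hardening protease inhibitor, at -1.08 ± 0.31. The panel ranged from Cyp17a1 at -0.72 ± 1.01 to Star at 1.31 ± 1.36, and the SE of Star was the widest of the 16.

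DiNP at 100 ug/kg/day was compared with control at 0 months for the effect of its higher dose. Macrophage genes were higher in 18 of 19 members, with a median of 0.45 (adjusted p = 1.53e-09; adjusted p = 0.751 with an estimated correlation). Adgre1, a macrophage surface receptor gene, differed by 0.81 ± 0.35 and C1qa by 0.64 ± 0.31, while Cd14 was at -0.08. Interferon response genes were higher in 22 of 22 members, with a median of 0.50 and Ifit1 at 1.15 ± 0.48 (adjusted p = 2.36e-12; adjusted p = 0.751 with an estimated correlation). Ovarian surface genes were lower in 11 of 13 members, with a median of -0.36, Lrrn4 at -1.10 ± 0.42 and Lhx9 at 0.19 (adjusted p = 5.28e-05; adjusted p = 0.64 with an estimated correlation). In these lists 0 members passed when adjusted over the list alone.

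With DiNP 100 at 0 months 4 calls ended without single libraries. Granulosa cell genes were lower in 12 of 20 members (median -0.23, adjusted p = 0.000637; adjusted p = 0.902 with an estimated correlation), with Inhbb at -0.86 ± 0.37, Nppc at -0.84 ± 0.37 and Kitl at 0.66. That call ended without control replicate 1 (mean -0.16) or DiNP 100 replicate 3 (-0.11). Unfolded protein response genes were lower in 17 of 21 members (median -0.25, adjusted p = 0.000181; adjusted p = 0.987 with an estimated correlation), with Hsp90b1 at -0.51 ± 0.28 and Asns at 0.23, but not without control replicate 2 (mean -0.18). Proliferation genes were lower in 28 of 30 members (median -0.09, adjusted p = 0.0177; adjusted p = 0.987 with an estimated correlation), with Ccnd2 at -0.46 ± 0.21. The list missed the threshold without control replicate 1 (mean -0.02), DiNP 100 replicate 2 (-0.08) or DiNP 100 replicate 3 (-0.06). Immediate early genes were lower in 17 of 21 members (median -0.23, adjusted p = 0.0264; adjusted p = 0.987 with an estimated correlation), with Dnajb1 at -0.43 ± 0.26 and Fos at 0.37, but not without control replicate 3 (mean -0.11) or DiNP 100 replicate 3 (-0.07).

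Limma called 0 genes for DiNP 100 at 0 months, and 258 had an unadjusted p under 0.05, a count that no left-out library moved by over 1.5 times. Obox2 differed by 3.87 ± 0.82, against the same control libraries, Mug1, a protease inhibitor gene, by 1.80 ± 0.47 and Aoah by 1.34 ± 0.38 (each adjusted p = 1). Smim24 was at -0.77 ± 0.20, Tspyl2 at -0.34 ± 0.09 and AI450353 at -0.79 ± 0.22. In the panel, Hsd17b1 (Entrez 15485, chromosome 11, 101077968 to 101081188), which makes estradiol from estrone, stood at 7.14 ± 0.27 against 7.88 ± 0.44 log2 CPM (-0.75 ± 0.32, adjusted p = 1). The other 15 panel genes ranged from Cyp17a1 at -1.37 ± 1.01 to Star at 1.04 ± 1.36.

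Across the 4 treated groups at 0 months, the interferon response, unfolded protein response and immediate early lists were the 3 called in the same direction each time. The interferon list mean was 2.24 ± 0.24 log2 CPM in controls, against 3.07 ± 0.51 with DEHP 20, 2.81 ± 0.26 with DEHP 200, 2.66 ± 0.21 with DiNP 20 and 2.86 ± 0.06 with DiNP 100. The 4 comparisons share 1 set of 3 control libraries, which cannot be split, so that part of what they share may come from those libraries. Across genes, which are not independent replicates, fold changes of pairs of treatments correlated at r = 0.41 to 0.69, and simulated data with no effect gave means of 0.499 to 0.502. Observed covariances were 0.041 to 0.06 against a simulated 0.061. A test for any treatment effect at 0 months called 0 genes in limma, with 325 at an unadjusted p under 0.05 and Foxa3 first. That number was 735 without DEHP 200 replicate 1 and 205 without DEHP 200 replicate 3, and Obox2 alone passed without control replicate 3. Obox2 groups overlapped in every comparison but that of DEHP 20.

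**Figure D1:**
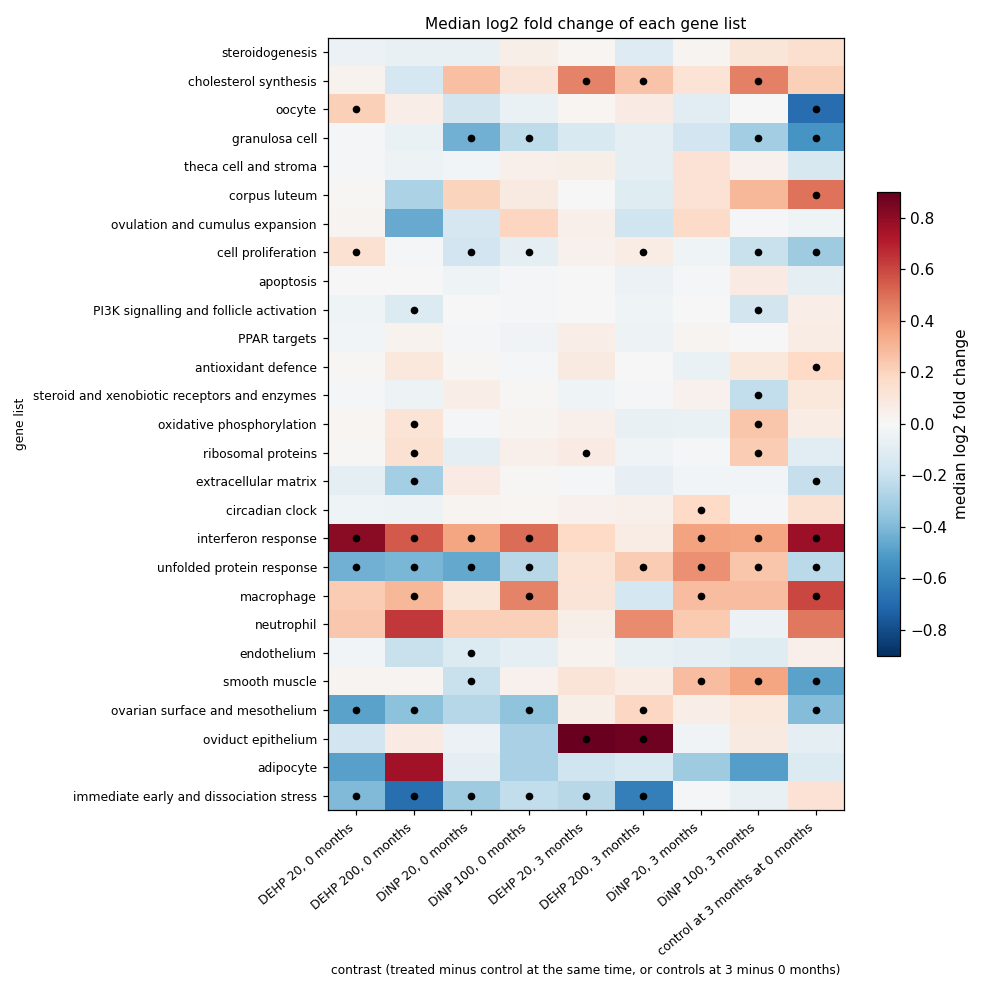
Median log2 fold change of 27 gene lists (vertical axis) in the 8 treated-versus-control comparisons and the control time comparison (horizontal axis), as colour. Black dots mark lists called by camera with the preset correlation; the interferon response list is higher and the unfolded protein response list lower in all 4 treatments at 0 months.

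At 3 months the question was what remained, or emerged, after the end of dosing. With DEHP 20 the oviduct epithelium list was higher in 11 of 11 members, with a median of 0.89 (adjusted p = 1.13e-10; adjusted p = 0.289 with an estimated correlation). Over the list alone 4 members passed, and 0 over all genes. They were Ovgp1, the oviduct glycoprotein gene (3.36 ± 1.12), the cilium regulator Foxj1 (3.16 ± 1.24), the cilium gene Cfap126 (1.49 ± 0.48) and the cadherin gene Cdh1 (1.35 ± 0.43). These are markers of a tissue next to the ovary, and DEHP 20 replicate 2 held a list mean of 4.51 log2 CPM against 2.10 ± 0.23 in controls. Without that library the list mean difference was 0.58 and the list was still called (adjusted p = 0.00948).

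For DEHP 20 at 3 months 3 more calls ended without single libraries. Cholesterol synthesis genes were higher in 23 of 24 members (median 0.45, adjusted p = 0.000767; adjusted p = 0.987 with an estimated correlation), with Hsd17b7 at -0.82. They were not called without DEHP 20 replicate 3 (mean 0.01), control replicate 1 (0.19) or control replicate 2 (0.25). Immediate early genes were lower in 17 of 21 members (median -0.25, adjusted p = 0.0281; adjusted p = 0.987 with an estimated correlation), with Egr2 at -1.32 ± 0.89 and Hspb1 at 0.61. Their call ended without DEHP 20 replicate 1 (mean -0.46), DEHP 20 replicate 2 (-0.25) or control replicate 2 (-0.02). Ribosomal protein genes were higher in 27 of 30 members (median 0.08, adjusted p = 0.0483; adjusted p = 0.987 with an estimated correlation), with Rps6 at 0.43 ± 0.28 and Rps27 at -0.94. The call did not hold without DEHP 20 replicate 1 (mean 0.03), DEHP 20 replicate 2 (0.06) or control replicate 3 (-0.06).

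Limma called 0 genes for DEHP 20 at 3 months, and 248 had an unadjusted p under 0.05. The number was 414 without DEHP 20 replicate 1, 164 without DEHP 20 replicate 2 and 465 without control replicate 1. Serpina1d (Entrez 20703, chromosome 12, 103763587 to 103773633), of the antitrypsin family, had the smallest p (2.11 ± 0.44, adjusted p = 1), at 1.89 ± 0.78 against -0.22 ± 0.75 log2 CPM. Tmem30b differed by 1.25 ± 0.32, the adhesion gene Flrt3 by 1.04 ± 0.28, Armc8 by -0.42 ± 0.12, Mzf1 by -0.80 ± 0.25 and Scml4 by -0.92 ± 0.31. The panel ranged from Cyp19a1 at -1.12 ± 0.85 to Star at 0.43 ± 1.36.

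With DEHP 200 at 3 months the oviduct epithelium list was again higher in 11 of 11 members, with a median of 0.88 (adjusted p = 3.58e-09; adjusted p = 0.31 with an estimated correlation). Foxj1 differed by 2.89 ± 1.24 and Cdh1 by 0.99 ± 0.43, and 0 members passed when adjusted over the list alone. Replicate 1 held a list mean of 4.01 log2 CPM, and without it the mean difference was 0.51 and the list still called (adjusted p = 0.00559). The remaining 5 calls ended or turned without single libraries. Genes of the unfolded protein response were higher in 19 of 21 members (median 0.23, adjusted p = 1.03e-05; adjusted p = 0.877 with an estimated correlation), with Dnajc3 at 0.26 ± 0.12 and Atf4 at -0.22, but not without control replicate 1 (mean 0.12) or DEHP 200 replicate 2 (0.01). Immediate early genes were lower in 19 of 21 members (median -0.62, adjusted p = 0.000135; adjusted p = 0.791 with an estimated correlation), with Nr4a1 at -1.43 ± 0.67 and Hspb1 at 0.58, but not without control replicate 2 (mean -0.20).

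Ovarian surface genes were higher in 11 of 13 members with DEHP 200 at 3 months (median 0.19, adjusted p = 0.0068; adjusted p = 0.874 with an estimated correlation), with Krt18 at 0.69 ± 0.26, but not without control replicate 3 (mean 0.15) or DEHP 200 replicate 2 (0.14). Cholesterol synthesis genes were higher in 21 of 24 members (median 0.26, adjusted p = 0.0128; adjusted p = 0.987 with an estimated correlation), with Stard4 at 0.44 ± 0.39 and Dhcr7 at -0.15. The list missed the threshold without control replicate 1 (mean 0.08), control replicate 2 (0.14), DEHP 200 replicate 1 (-0.02) or DEHP 200 replicate 3 (0.06). Proliferation genes were higher in 20 of 30 members (median 0.07, adjusted p = 0.0414; adjusted p = 0.987 with an estimated correlation), with the replication gene Mcm4 at 0.31 ± 0.17 and Aurkb at -0.17. Without control replicate 3 the same list was lower (mean -0.15, adjusted p = 0.0139), and without DEHP 200 replicate 2 it was not called (mean 0.03).

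For DEHP 200 at 3 months limma called 0 genes and 212 had an unadjusted p under 0.05, or 510 without control replicate 1. Faim2, an inhibitor of Fas-mediated cell death, differed by 1.86 ± 0.44 (adjusted p = 1), at 1.27 ± 0.37 against -0.59 ± 0.45 log2 CPM. Ccdc89 differed by 0.95 ± 0.26, with overlapping groups, and Tmem30b by 1.01 ± 0.32. Vezt was at -0.30 ± 0.09, the peroxisomal carrier Slc25a17 at -0.40 ± 0.12 and Npffr1 at -0.82 ± 0.25. The panel ranged from Kitl at -0.64 ± 0.75 to Amh at 0.49 ± 0.38.

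DiNP 20 at 3 months gave 5 calls, all higher than control. The unfolded protein response list was higher in 21 of 21 members, with a median of 0.41, Hspa5 (BiP) at 0.60 ± 0.26 and Dnajc3 at 0.37 ± 0.12 (adjusted p = 5.61e-12; adjusted p = 0.64 with an estimated correlation). Genes of the interferon response were higher in 19 of 22 members, with a median of 0.36, Ifit3 at 1.56 ± 0.55 and Rsad2 at -0.72 (adjusted p = 5.37e-07; adjusted p = 0.893 with an estimated correlation). Both calls remained without any library, but the first list's mean of 0.41 was 0.26 without control replicate 1 and 0.14 without DiNP 20 replicate 3. The interferon mean of 0.40 was 0.25 without DiNP 20 replicate 1. In both 0 members passed when adjusted over the list alone. Clock genes were higher in 14 of 19 members (median 0.18, adjusted p = 0.0068; adjusted p = 0.767 with an estimated correlation), with Per2 at 0.66 ± 0.30 and Per1 at -0.19, but not without control replicate 1 (mean 0.08), control replicate 2 (0.16) or DiNP 20 replicate 2 (0.11). Macrophage genes were higher in 17 of 19 members (median 0.28, adjusted p = 0.00022; adjusted p = 0.987 with an estimated correlation), with Cd14 at 0.43 ± 0.22 and Lyz2 at -0.29, but not without DiNP 20 replicate 1 (mean -0.02). Smooth muscle genes were higher in 11 of 11 members (median 0.28, adjusted p = 0.000321; adjusted p = 0.877 with an estimated correlation), with Lmod1 at 0.32 ± 0.20, but not without control replicate 3 (mean 0.19) or DiNP 20 replicate 2 (0.02).

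For DiNP 20 at 3 months limma called 0 genes and 224 had an unadjusted p under 0.05, a count that no left-out library moved by over 1.5 times. Prag1 differed by 0.52 ± 0.13 (adjusted p = 1), the complement gene C4b by 1.32 ± 0.37 and Fgl2 by 0.44 ± 0.14. Lmtk3 was at -1.76 ± 0.54, Commd10 at -0.32 ± 0.10 and Zdhhc15 at -0.46 ± 0.15. The panel ranged from Cyp19a1 at -0.69 ± 0.85 to Cyp17a1 at 0.75 ± 1.01.

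DiNP 100 at 3 months had the highest count at an unadjusted p among the treated-versus-control comparisons, 1368 genes, of which 644 were higher and 724 lower, and limma called 0. That number was 800 without control replicate 1, 3970 without DiNP 100 replicate 2 and 207 without DiNP 100 replicate 3. Without DiNP 100 replicate 2, 633 genes passed, 317 higher and 316 lower, and 0 passed without replicate 1 or without replicate 3. Replicates 1 and 3, the treated libraries left in that comparison, stood apart from the other 28 libraries in having the most genes at the lowest value of the table (167 and 187) and the highest column sums (1094293 and 1164842). Their scores on principal component 1 were 51.7 and 45.6 against 5.7 in replicate 2, and their array weights were the lowest of all, 0.00491 and 0.21. Abcb4 (Entrez 18670, chromosome 5, 8893614 to 8959226), a phospholipid transporter gene, stood at 4.63, 0.65 and 4.94 log2 CPM in replicates 1 to 3 against 0.23 ± 0.11 in controls. It differed by 3.18 ± 0.81 with all libraries (adjusted p = 0.518) and by 4.56 without replicate 2 (adjusted p = 0.00323).

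Inhba (Entrez 16323, chromosome 13, 16004256 to 16031609), the inhibin and activin beta A subunit of growing follicles, stood at 6.38 ± 0.89 with DiNP 100 at 3 months against 7.78 ± 0.15 log2 CPM in controls (-1.39 ± 0.42, adjusted p = 0.518). Without DiNP 100 replicate 2 it passed, at -1.83 (adjusted p = 0.0434). The other 15 panel genes ranged from Kitl at -1.06 ± 0.75 to Star at 1.03 ± 1.36. Rsph3b (chromosome 17, 6904716 to 6948356) differed by 1.33 ± 0.32 and Tagap (7926000 to 7934897), near it, by 1.61 ± 0.39. Both passed without replicate 2, at 1.49 and 1.73 (adjusted p = 0.0434 and 0.0442). Both were nearly as high in single libraries of DEHP 20 and DiNP 20 (5.14 to 5.34 and 3.84 to 3.95 log2 CPM). Ttc9c was at -0.29 ± 0.08, Zfp738 at -1.07 ± 0.29 and Lyve1, a lymphatic endothelial receptor gene, at -1.14 ± 0.32.

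All 10 list calls for DiNP 100 at 3 months ended without at least 1 library. Oxidative phosphorylation genes were higher in 24 of 24 members (median 0.25, adjusted p = 8.41e-06; adjusted p = 0.987 with an estimated correlation), with Ndufb8 at 0.51 ± 0.18, but not without DiNP 100 replicate 3 (mean 0.05). Ribosomal protein genes were higher in 29 of 30 members (median 0.23, adjusted p = 1.54e-06; adjusted p = 0.987 with an estimated correlation), with Rpl19 at 0.38 ± 0.16, but not without control replicate 3 (mean 0.11) or DiNP 100 replicate 3 (-0.01). Granulosa cell genes were lower in 18 of 20 members (median -0.31, adjusted p = 0.00954; adjusted p = 0.987 with an estimated correlation), with Foxl2 at 0.33, but not without control replicate 1 (mean -0.24), DiNP 100 replicate 1 (-0.27) or DiNP 100 replicate 2 (-0.38). Proliferation genes were lower in 27 of 30 members (median -0.20, adjusted p = 0.00341; adjusted p = 0.987 with an estimated correlation), with Ccne2 at -0.45 ± 0.23 and Ccne1 at 0.21, but not without control replicate 1 (mean 0.01) or DiNP 100 replicate 1 (-0.14). The interferon response list was higher in 20 of 22 members (median 0.36, adjusted p = 0.00907; adjusted p = 0.987 with an estimated correlation), with Ifit3 at 1.49 ± 0.55, but not without DiNP 100 replicate 1 (mean 0.05).

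Among the weaker calls for DiNP 100 at 3 months were cholesterol synthesis genes, higher in 23 of 24 members (median 0.45, adjusted p = 0.0281; adjusted p = 0.987 with an estimated correlation), with Fdft1 at 0.46 ± 0.33 and Hsd17b7 at -1.45. They were not called without control replicate 1 (mean 0.22), control replicate 2 (0.28), DiNP 100 replicate 1 (0.36) or DiNP 100 replicate 2 (0.56). Smooth muscle genes were higher in 11 of 11 members (median 0.36, adjusted p = 0.034; adjusted p = 0.987 with an estimated correlation), with Lmod1 at 0.54 ± 0.20, but not without control replicate 3 (mean 0.20) or DiNP 100 replicate 2 (0.25). PI3K signalling genes were lower in 17 of 22 members (median -0.17, adjusted p = 0.0382; adjusted p = 0.791 with an estimated correlation), with Tsc1 at -0.34 ± 0.15 and Akt1 at 0.16, but not without control replicate 3 (mean -0.20) or DiNP 100 replicate 3 (-0.12). Steroid and xenobiotic receptor genes were lower in 14 of 17 members (median -0.22, adjusted p = 0.0351; adjusted p = 0.874 with an estimated correlation), with the dioxin receptor gene Ahr at -0.49 ± 0.26 and Ephx2 at 0.65. That call ended without control replicate 1 (mean -0.20), control replicate 3 (-0.23), DiNP 100 replicate 1 (-0.15) or DiNP 100 replicate 3 (-0.13). Unfolded protein response genes were higher in 20 of 21 members (median 0.25, adjusted p = 0.0447; adjusted p = 0.987 with an estimated correlation), with Atf4 at 0.35 ± 0.21, but not without control replicate 1 (mean 0.12), control replicate 3 (0.27) or DiNP 100 replicate 2 (0.15).

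At 3 months 0 lists were called in 1 direction in all 4 treatments. Fold changes of pairs of treatments correlated across genes, which are not independent replicates, at r = 0.165 for DEHP 200 and DiNP 100 to 0.588 for DEHP 20 and DEHP 200. Simulated data with shared controls and no effect gave 0.499 to 0.503, and observed covariances were 0.015 to 0.046 against a simulated 0.06 to 0.061. A test for any treatment effect at 3 months called 0 genes in limma, with 588 at an unadjusted p under 0.05 and Dnah11, a motile cilium gene, first. It stood at 3.07 log2 CPM in DEHP 20 replicate 2 and 3.35 in DEHP 200 replicate 1, at 1.18 to 2.06 in the other 4 DEHP libraries of 3 months and at most 1.01 in the 9 without DEHP. The number at an unadjusted p was 2527 without DiNP 100 replicate 2 and 245 without DiNP 100 replicate 3. Without DiNP 100 replicate 2, 5 genes passed, namely Rpl14-ps1, Abcb4, Lancl3, Zfp442 and Gipc1, named after their values were seen. Steroidogenesis, theca and stroma, ovulation, apoptosis, PPAR target, neutrophil and adipocyte lists were called in none of the 9 comparisons tested first.

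**Figure D2:**
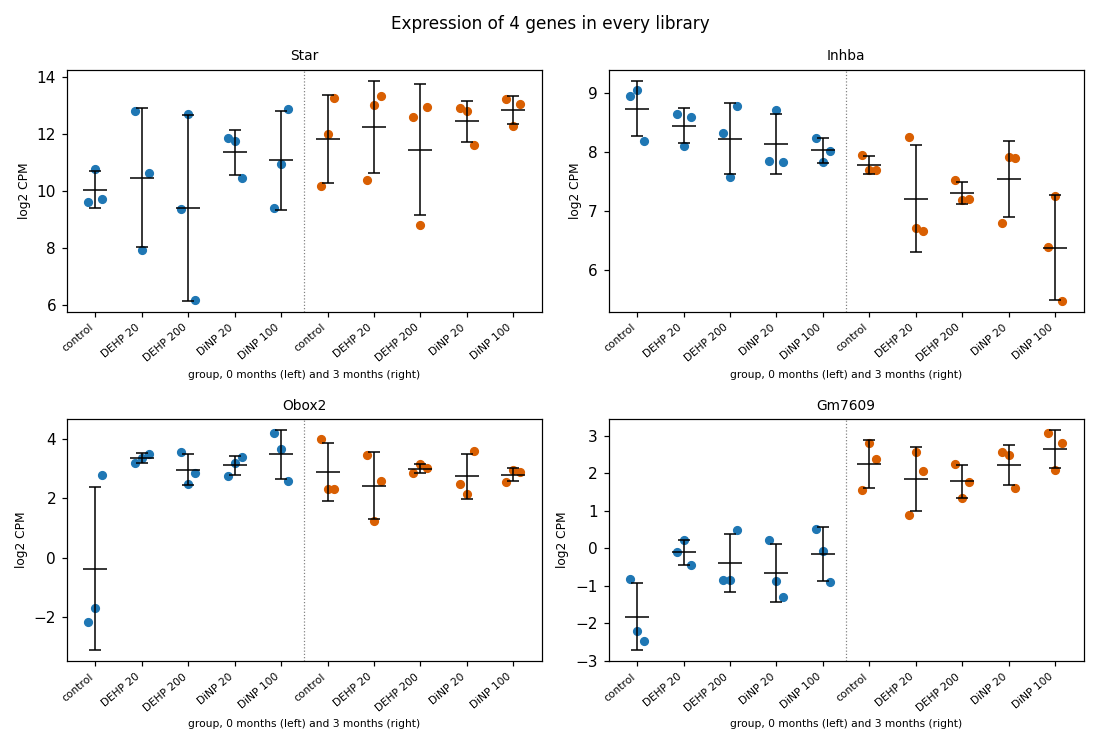
Log2 CPM of Star, Inhba, Obox2 and Gm7609 (vertical axes) in each of 30 libraries by group (horizontal axis), with mean and SD. Obox2 is near absent in 2 control libraries at 0 months, and Inhba is lowest with DiNP 100 at 3 months, at a mean of 6.38 log2 CPM.

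The compounds were compared at the dose they share, 20 ug/kg/day, for a difference between DEHP and DiNP. At 0 months Inha (Entrez 16322, chromosome 1, 75507077 to 75510366), the inhibin alpha subunit, differed by 0.60 with a 95% interval of 0.04 to 1.15 (adjusted p = 1). Esr1 differed by 0.45 (-0.04 to 0.94), Hsd3b1 by 0.10 (-0.61 to 0.81) and Star by -0.90 (-3.72 to 1.93). The zinc finger gene Zkscan3 had the smallest p, at -0.49 (-0.76 to -0.23, adjusted p = 1). Limma called 0 genes, and 302 had an unadjusted p under 0.05, or 762 without DiNP 20 replicate 3. Of the gene lists, tested here only after the data were seen, granulosa cell genes (median 0.30, 19 of 20 members) and proliferation genes (0.33, 29 of 30) were higher with DEHP. The proliferation mean of 0.33 was 0.19 without DiNP 20 replicate 1 and 0.53 without DiNP 20 replicate 3. Oocyte genes (0.36, 23 of 24 members) were higher except without DEHP 20 replicate 2 (mean 0.18), and interferon response genes (0.44, 20 of 22) except without DEHP 20 replicate 1 (0.21). Ovarian surface genes (-0.37, 11 of 13 members) were lower except without DEHP 20 replicate 1 (-0.21) or DiNP 20 replicate 2 (-0.15). All 5 had an adjusted p = 0.995 with an estimated correlation.

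At 3 months oviduct epithelium genes were higher with DEHP 20 than with DiNP 20 in 10 of 11 members, with a median of 1.04 (adjusted p = 0.344 with an estimated correlation), and 5 members passed over the list alone. The mean difference of 1.29 was 0.68 without DEHP 20 replicate 2, whose list mean of 4.51 log2 CPM stood apart, and the list was still called. Genes of the unfolded protein response were lower with DEHP in 19 of 21 members (median -0.31), but not without DiNP 20 replicate 3 (mean -0.04). Immediate early genes were lower in 19 of 21 members (-0.26), but not without DEHP 20 replicate 2 (-0.32) or DiNP 20 replicate 3 (-0.07). Interferon response genes were lower in 15 of 22 members (-0.23), but not without DEHP 20 replicate 1 (0.04), DEHP 20 replicate 3 (-0.10) or DiNP 20 replicate 1 (-0.08). These 3 lists had an adjusted p = 0.995 with an estimated correlation. Armc8 differed by -0.60 with a 95% interval of -0.85 to -0.35 (adjusted p = 0.56) and was the gene with the smallest p. Hsd3b1 differed by 0.01 (-0.71 to 0.72) and Star by -0.20 (-3.02 to 2.63). Limma called 0 genes, and 427 had an unadjusted p under 0.05, a count that no left-out library moved by over 1.5 times. DEHP 200 and DiNP 100 were not compared with each other, since their doses differ.

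The doses of each compound were compared to ask for a difference between low and high exposure, and limma called 0 genes in all 4 comparisons. In DEHP 200 against DEHP 20 at 0 months the forkhead gene Foxa3 (Entrez 15377, chromosome 7, 19013283 to 19023539) was nearest to passing (1.65 ± 0.28, adjusted p = 0.0666), at 1.63 ± 0.22 against -0.02 ± 0.27 log2 CPM. There 582 genes had an unadjusted p under 0.05, or 1527 without DEHP 200 replicate 1. In DiNP 100 against DiNP 20 at 0 months Thg1l differed by 0.71 ± 0.21 (adjusted p = 1). There the count was 86, or 190 without DiNP 20 replicate 2, 194 without DiNP 20 replicate 3 and 181 without DiNP 100 replicate 3. In DEHP 200 against DEHP 20 at 3 months Ahsg (fetuin A) differed by -1.78 ± 0.46 (adjusted p = 1). The count was 141, or 245 without DEHP 20 replicate 1 and 250 without DEHP 200 replicate 2. In DiNP 100 against DiNP 20 at 3 months Morn1 differed by 0.73 ± 0.16 (adjusted p = 0.405), and 1794 genes had an unadjusted p under 0.05. That count was 1118 without DiNP 20 replicate 3, 4151 without DiNP 100 replicate 2 and 277 without DiNP 100 replicate 3, and 1336 genes passed without DiNP 100 replicate 2.

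List calls between doses all had an adjusted p = 0.995 with an estimated correlation. In DEHP at 0 months adipocyte genes were higher at 200 (median 1.09), but not without DEHP 20 replicates 1 (mean 0.86) or 3 (0.63) or DEHP 200 replicates 1 (0.97) or 3 (0.64). Without DEHP 200 replicate 3 the lower extracellular matrix (-0.28) and higher ribosomal protein (0.16) calls ended, at means of -0.02 and 0.08. The lower proliferation list (-0.16) was not called without DEHP 20 replicate 1 (-0.07) or DEHP 200 replicates 1 (-0.11) or 2 (-0.004). The lower interferon list (-0.23) was not called without DEHP 20 replicates 1 (-0.06) or 3 (-0.17) or DEHP 200 replicates 1 (-0.12) or 3 (-0.28). In DiNP at 0 months 6 lists were called and each ended without at least 1 library. Macrophage (median 0.30) and smooth muscle genes (0.27) were higher at 100, but at means of 0.01 and 0.12 not without DiNP 20 replicate 3. Interferon genes were higher (0.22), but not without DiNP 20 replicate 1 (0.08), and unfolded protein response genes (0.19), but not without DiNP 20 replicate 1 (0.14) or DiNP 100 replicate 3 (0.11). Ribosomal protein genes were higher (0.13), but not without DiNP 20 replicates 1 (0.06) or 2 (0.01) or DiNP 100 replicate 1 (0.01). Ovarian surface genes were lower (-0.14), but not without DiNP 20 replicates 1 (-0.16) or 2 (-0.03) or DiNP 100 replicates 2 (-0.12) or 3 (-0.21).

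At 3 months unfolded protein response genes were higher at DEHP 200 than at DEHP 20 (median 0.18), but not without DEHP 20 replicate 3 (mean 0.06) or DEHP 200 replicate 2 (-0.09). Macrophage genes were lower (-0.28), but not without DEHP 20 replicate 2 (0) or DEHP 200 replicate 1 (-0.12). Oxidative phosphorylation genes were lower (-0.10), but not without DEHP 200 replicate 2 (-0.02), and ribosomal protein genes (-0.11), but not without DEHP 20 replicate 1 (-0.06) or DEHP 200 replicate 1 (0). With DiNP 100 against DiNP 20, oxidative phosphorylation (0.31) and ribosomal protein genes (0.25) were higher, but at means of 0.09 and 0.04 not without DiNP 100 replicate 3. PI3K signalling genes were lower (-0.20), but not without DiNP 20 replicate 1 (-0.19) or DiNP 100 replicate 3 (-0.14). Steroid and xenobiotic receptor genes were lower (-0.26), but not without DiNP 20 replicate 2 (-0.20) or DiNP 100 replicate 1 (-0.19).

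Each treatment's effect at 3 months was tested against its effect at 0 months to ask whether the response changed after dosing ended. Limma called 0 genes in all 4 tests. For DEHP 20, 289 genes had an unadjusted p under 0.05 and Serpina1d had the smallest p (2.79 ± 0.62, adjusted p = 1). For DEHP 200 there were 375, or 814 without DEHP 200 replicate 1 of 0 months, and Faim2 was first (2.64 ± 0.62, adjusted p = 1). For DiNP 20 there were 219, or 332 without control replicate 1 of 3 months, and Npr1, a natriuretic peptide receptor gene, was first (0.69 ± 0.19, adjusted p = 1). For DiNP 100 there were 343, and Tspyl2 was first (0.48 ± 0.13, adjusted p = 0.997). That count was 180 without control replicate 1 of 0 months and 539, 1711 and 164 without DiNP 100 replicates 1, 2 and 3 of 3 months. Obox2 passed in all 4 tests without control replicate 3 of 0 months.

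Controls at 3 months were compared with controls at 0 months for the change with time alone, which also carries age and the day of collection. Oocyte genes were lower in 24 of 24 members, with a median of -0.69 (adjusted p = 1.88e-11; adjusted p = 0.874 with an estimated correlation). Over the list alone 3 members passed, Sohlh1 (-1.64 ± 0.40), the germ cell helicase gene Ddx4 (-1.33 ± 0.37) and Figla (-0.97 ± 0.31), and 0 over all genes. Without replicate 3 of 3 months the list's mean went from -0.71 to -0.38 and it was still called. Granulosa cell genes were lower in 19 of 20 members, with a median of -0.53 and Kitl at 0.30 (adjusted p = 1.28e-06; adjusted p = 0.751 with an estimated correlation), and 1 passed over the list alone, Nppc (-1.26 ± 0.37). Proliferation genes were lower in 30 of 30 members, with a median of -0.32 and Ccnd2 at -0.65 ± 0.21 (adjusted p = 2.62e-09; adjusted p = 0.877 with an estimated correlation). Their mean of -0.36 was -0.58 without replicate 1 and -0.14 without replicate 3 of 3 months, called in both. Macrophage genes were higher in 19 of 19 members, with a median of 0.60 (adjusted p = 2.77e-09; adjusted p = 0.751 with an estimated correlation). Over the list alone 6 of them passed, among them Csf1r (0.88 ± 0.26) and C1qa (0.94 ± 0.31). Genes of the interferon response were higher in 21 of 22 members, with a median of 0.77 (adjusted p = 2.77e-09; adjusted p = 0.813 with an estimated correlation), and 8 passed over the list alone, among them Ifih1 (0.77 ± 0.26) and Ifi44 (1.62 ± 0.56).

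Smooth muscle genes were lower with time in 10 of 11 members, with a median of -0.48 and Tagln at -0.68 ± 0.27 (adjusted p = 0.00117; adjusted p = 0.936 with an estimated correlation). Ovarian surface genes were lower in 12 of 13 members, with a median of -0.39, Msln at -1.27 ± 0.51 and Krt8 at 0.25 (adjusted p = 0.00546; adjusted p = 0.874 with an estimated correlation). Another 4 calls ended without single libraries. Extracellular matrix genes were lower in 23 of 28 members (median -0.21, adjusted p = 0.00339; adjusted p = 0.987 with an estimated correlation), with Eln at -0.58 ± 0.24 and Mmp9 at 1.03, but not without replicate 1 of 3 months (mean -0.07). The unfolded protein response list was lower in 18 of 21 members (median -0.24, adjusted p = 0.00144; adjusted p = 0.987 with an estimated correlation), with Hyou1 at -0.62 ± 0.22 and Chac1 at 0.86. The call did not hold without replicate 2 of 0 months (mean -0.18) or replicate 1 of 3 months (-0.11). Antioxidant genes were higher in 18 of 22 members (median 0.18, adjusted p = 0.0264; adjusted p = 0.987 with an estimated correlation), with Sod3 at 0.49 ± 0.21, but not without replicate 3 of 3 months (mean 0.13). Corpus luteum genes were higher in 14 of 15 members (median 0.49, adjusted p = 0.0418; adjusted p = 0.987 with an estimated correlation), with Star at 1.78 ± 1.36. The list missed the threshold without replicate 1 (mean 0.67) or 2 (0.83) of 0 months or replicate 2 (0.71) or 3 (0.45) of 3 months.

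In controls limma called 1 gene between the time points. Gm7609 (Entrez 665378, chromosome 1, 85199592 to 85215398), a predicted gene, rose by 4.07 ± 0.53 (adjusted p = 0.00125), from -1.82 ± 0.89 to 2.25 ± 0.64 log2 CPM. Skap2 stood at 4.98 ± 0.15 against 4.41 ± 0.16 (0.57 ± 0.10, adjusted p = 0.0849). Without replicate 3 of 0 months 3 genes passed, Obox2, Skap2 and Gm7609, and without replicate 1 of 3 months 2 passed, Sema6c and Gm7609. With all libraries 1176 genes had an unadjusted p under 0.05. That count was 622 without replicate 1 of 0 months, 2202 without replicate 1 of 3 months and 423 without replicate 3 of 3 months.

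**Figure D3:**
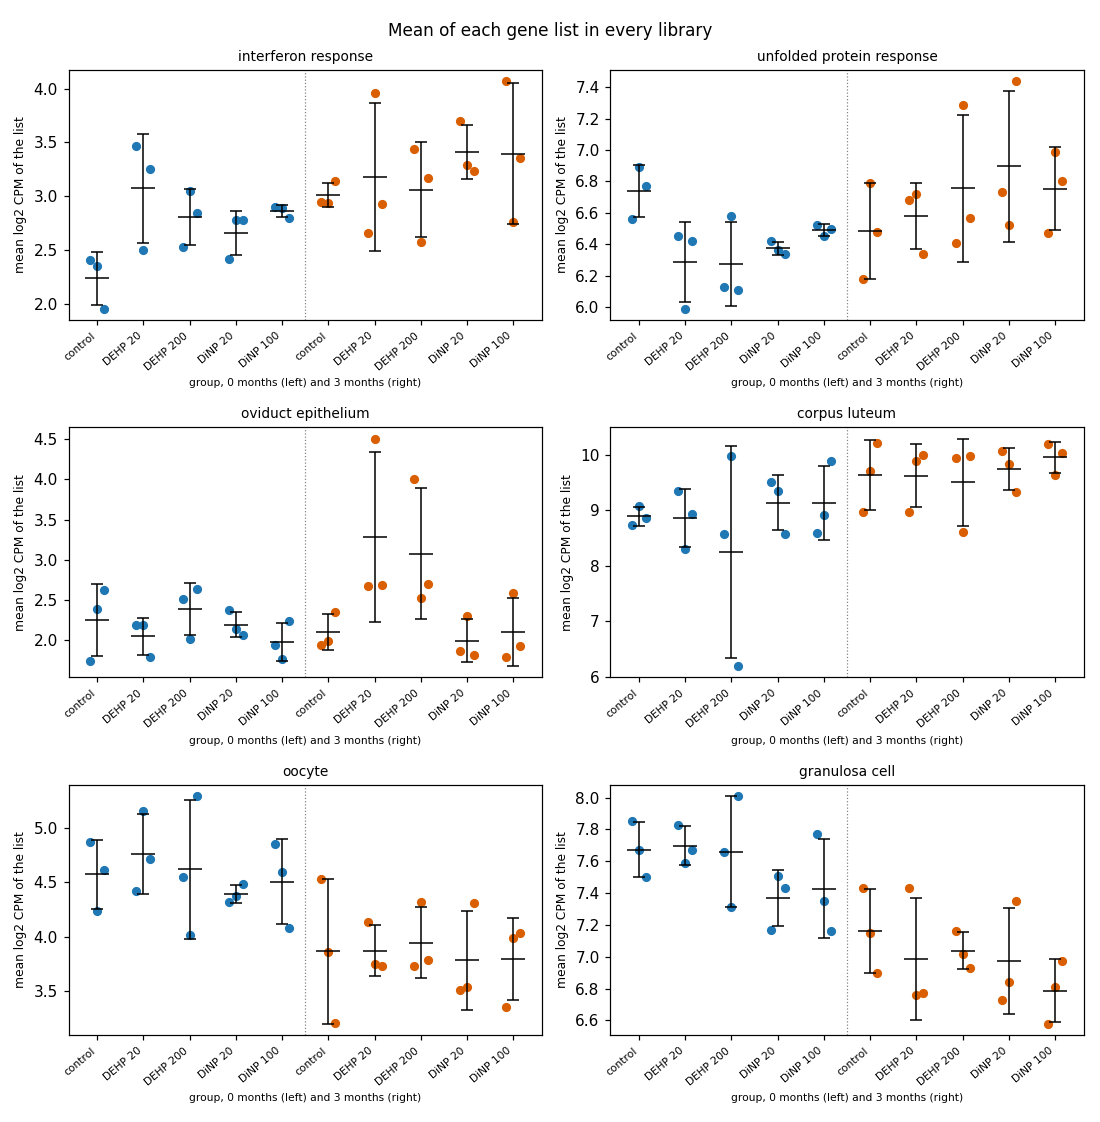
Mean log2 CPM of 6 gene lists (vertical axes) in each of the 30 libraries by group (horizontal axis), blue for 0 months and orange for 3 months, with group mean and SD. The oviduct list reaches 4.51 and 4.01 log2 CPM in 1 library each of DEHP 20 and DEHP 200 at 3 months, and the corpus luteum list falls to 6.19 in 1 library of DEHP 200 at 0 months.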

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

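The tests of gene lists between time points, and the tests of Obox2 in this part other than that of its neighbouring genes, were chosen only after the results were seen, as were the test of the other DEHP libraries for the oviduct list and that of the control libraries for the interferon list. The neighbouring gene, motile cilium and macrophage tests were written down before their values were computed. Each value in the next paragraphs is the median log2 difference of a list between a treatment's effect at 3 months and at 0 months, given because that difference passed camera with the preset correlation. None of the 21 held with an estimated correlation, where the lowest adjusted p was 0.344. Adjusted over the list alone, 8 unfolded protein response genes passed for DiNP 20 and 5 for DEHP 200, and 1 ovarian surface gene for DEHP 20, with 0 over all genes.

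With DEHP 20, interferon response genes differed between time points by -0.59, unfolded protein response genes by 0.52, ovarian surface genes by 0.53 and oviduct epithelium genes by 1.13. These 4 calls remained without any single library, but the oviduct mean of 1.39 was 0.78 without DEHP 20 replicate 2 of 3 months, and the interferon mean of -0.66 was -0.40 without replicate 1 and -1.05 without replicate 2 of 3 months. With DEHP 200, unfolded protein response genes differed by 0.71 and ovarian surface genes by 0.41, without any library ending the call, although the mean of the first list went from 0.74 to 0.48 without DEHP 200 replicate 2 of 3 months. The oviduct epithelium list (0.67) was not called without DEHP 200 replicate 1 of 3 months (mean 0.37), nor the interferon response list (-0.39) without its replicate 2 of 3 months (-0.27). Macrophage genes (-0.38) were not called without control replicate 1 of 0 months (-0.28), DEHP 200 replicate 2 of 0 months (-0.23) or replicate 1 of 3 months (-0.23).

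Also with DEHP 200, oxidative phosphorylation genes differed by -0.19, but not without replicate 2 of 0 months (mean 0.02) or of 3 months (-0.09). Ribosomal protein genes differed by -0.18, but not without control replicate 1 of 3 months (-0.16), DEHP 200 replicate 3 of 0 months (-0.17) or replicate 1 of 3 months (-0.17). Extracellular matrix genes differed by 0.25, but not without control replicate 1 of 3 months (0.14), DEHP 200 replicate 3 of 0 months (0.07) or replicate 3 of 3 months (0.20). Cholesterol synthesis genes differed by 0.5. That call ended without control replicate 3 of 0 months (0.32), control replicates 1 (0.34) or 2 (0.40) of 3 months, DEHP 200 replicates 1 (0.48) or 3 (0.02) of 0 months, or replicates 1 (0.25) or 3 (0.32) of 3 months.

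With DiNP 20, unfolded protein response genes differed between time points by 0.87, without any library ending the call, although their mean went from 0.78 to 0.51 without DiNP 20 replicate 3 of 3 months. Smooth muscle genes differed by 0.52, but not without DiNP 20 replicate 2 of 3 months (mean 0.22). Immediate early and dissociation stress genes differed by 0.31, but not without control replicate 3 of 0 months (0.37), control replicate 1 of 3 months (0.27), or DiNP 20 replicate 3 of 0 months (0.31) or of 3 months (0.14).

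With DiNP 100, unfolded protein response genes differed by 0.52, without any library ending the call. Ovarian surface genes differed by 0.48, but not without control replicate 3 of 0 months (mean 0.32) or of 3 months (0.30) or DiNP 100 replicate 2 of 3 months (0.31). Oxidative phosphorylation genes differed by 0.22, but not without DiNP 100 replicate 3 of 3 months (-0.001). Ribosomal protein genes differed by 0.21, but not without control replicate 3 (0.01) or DiNP 100 replicate 3 (-0.11) of 3 months. Steroid and xenobiotic receptor genes differed by -0.22. That call ended without control replicates 1 (-0.18) or 2 (-0.20) of 0 months, control replicates 1 (-0.22) or 3 (-0.24) of 3 months, DiNP 100 replicates 1 (-0.19) or 2 (-0.24) of 0 months, or replicates 1 (-0.16) or 3 (-0.14) of 3 months.

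Obox2 was near absent in control replicates 1 and 2 at 0 months, at -2.19 and -1.72 log2 CPM, where the 12 treated libraries at 0 months had 2.5 to 4.2. Reads shared with its near-identical copies remain open, since the summed CPM of Obox1 and Obox5, 22.9 and 13.3, lay inside the range of the other 28 libraries (8.5 to 27.4), and with Obox2 added 23.1 lay inside and 13.6 just below it (14.3 to 41.1). Fewer oocytes would have lowered the oocyte list, but its means of 4.87 and 4.24 also lay inside the others' range (3.21 to 5.29). Obox2 was not low in 1 of 3 controls at 0 months (2.78) or in controls of 3 months (2.3 to 4.01). A rise under all 4 treatments at 0 months still remains open. So does a strain variant, since 0 of the 21 neighbouring genes within 1 Mb were missing in the same libraries, and a variant of Obox2 alone could not be tested with this table.

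For the oviduct epithelium list, oviduct tissue carried over in DEHP 20 replicate 2 and DEHP 200 replicate 1 of 3 months would also raise cilium genes outside the list. The mean of 17 such genes was 3.27 and 2.93 log2 CPM there, and the lower of these lay 1.01 above the highest of the other 28 libraries. Of the list itself, by which the 2 libraries were picked, Foxj1 stood at 5.78 and 4.91 against at most 2.63 elsewhere, but Ovgp1, at 6.35 in the first, reached 5.75 in another library, and Pax8 at 1.14 and 0.76 lay below the highest other (1.88). A rise in every DEHP library at 3 months would lift the remaining libraries too, and 4 of 4 had list means (2.52 to 2.69) above the highest control of that time point (2.35), but 2 of 18 libraries without DEHP also reached that range, control replicate 3 of 0 months (2.62) and DiNP 100 replicate 2 of 3 months (2.58). The cilium values go with carried-over tissue in the first 2 libraries, and a rise in the other DEHP libraries remains open.

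For the interferon response list at 0 months, macrophage content of the libraries would take the difference away once the macrophage list is a covariate. With that covariate the medians were 0.76 and 0.46 for low and high DEHP and 0.27 and 0.36 for DiNP (mean 0.46, 0.56 without). This speaks against macrophage content as the main source, most clearly for DEHP. At or below the highest control (2.41 log2 CPM) lay 0 of the other 27 libraries, the lowest of which had 2.42. Controls of 3 months had 2.94 to 3.14, and treated means of 0 months were 2.66 to 3.07. That goes with low 0-month controls, but time also differs, so that a true effect remains open. Interferon differences between time points use the same 0-month controls. Random regroupings of the libraries at 0 months called at least 3 lists the same way in all 4 treatments in 17 of 100, where the real number was 3 and the highest other 6, so that chance cannot be excluded.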

How the results depend on the processing

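The count of 0 genes held in every treated-versus-control, compound, dose and time-by-treatment comparison under median centring, no filter, an added pseudocount, robust fits, quantile normalization, list means as covariates and a 1.5-fold minimum. The control time comparison held at 1 gene, Gm7609, in the same settings. Each time point fitted alone, run for comparisons within a time point, also gave 0 genes throughout, as did adjustment over the 8 treated-versus-control comparisons together, run for those 8. With the stricter filter the control time comparison called 0. Fitting only the groups of the comparison, with fewer libraries for the variance, called 0 there, 1 gene each for DEHP 20 (Gm6644), DEHP 200 (Hmga1b) and DiNP 100 (Hmga1b) against control at 0 months, and 2 for DiNP 100 against DiNP 20 at 3 months (Hbb-bs and Gvin1). Fits with no trend called 1 gene, Foxa3, for DEHP 200 against DEHP 20 at 0 months. An adjusted p under 0.10 also called 1 gene there and 4 in the control time comparison (Bmi1, Ckb, Skap2 and Gm7609). Replicate number as a block changed no count of this paragraph. The replicates share only a number, and libraries with the same number correlated at r = -0.454 to 0.388 in their deviations from group means, so that the number pairs no samples. Except for the smaller sets of genes or libraries, the cause was not tested.

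Array weights ran from 0.00491 (DiNP 100 replicate 1 of 3 months) to 35.1 (control replicate 2 of 3 months), and the estimate stopped with a warning before it had settled. With them 1781 genes passed for DEHP 20, 1481 for DEHP 200 and 788 for DiNP 20 against control at 3 months, and 3567 in the control time comparison. The test for any treatment at 3 months called 2105. DEHP 20 against DiNP 20 at 3 months called 3 (Fank1, Flrt3 and Armc8), and DEHP 200 against DEHP 20 at 0 months called 1 (Foxa3). The effect at 3 months against 0 months called 318 for DEHP 20, 1 for DEHP 200 and 4 for DiNP 20. The cause was not tested.

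Leaving out single libraries gave 0 to 1 genes for each of the 4 treatments against control at 0 months, for each treatment's effect at 3 months versus 0 months, and for any treatment at 0 months, the highest each time without control replicate 3 of 0 months. It gave 1 to 3 for the control time comparison and 0 to 5 for any treatment at 3 months. For DiNP 100 at 3 months it gave 0 to 633 against control and 0 to 1336 against DiNP 20, the highest without DiNP 100 replicate 2. The other comparisons gave 0 throughout. Of the list calls 297 combinations kept the call, 92 lost it, and 1 reversed. That was the proliferation list in DEHP 200 against control at 3 months, at a mean of -0.149 without control replicate 3 and 0.289, the highest, without control replicate 1. The 65 list calls became 58 to 75, and 0 with an estimated correlation and 0 with fry. Without filter 4 list calls were lost, with quantile normalization 7, with the block 1 (ribosomal proteins with DEHP 20 at 3 months), and with median centring 0. Leaving out 4 libraries together, chosen after the data were seen, lost 11 calls and left the control time comparison at 2 genes (Adh7 and Gm7609). They were DEHP 200 replicate 3 of 0 months for its corpus luteum list, DEHP 20 replicate 2 and DEHP 200 replicate 1 of 3 months for their oviduct epithelium list, and DiNP 100 replicate 3 of 3 months for its place on principal component 3. DEHP 200 replicate 2 of 0 months and DiNP 100 replicate 1 of 3 months, which also stood apart, were left out only singly.

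The time effect over all 5 groups, 2986 genes, was 2147 to 4389 without single libraries. It was 1231 without the 4 libraries, 725 with at least 1.5-fold, 716 with oviduct and adipocyte list means as covariates, 135 with corpus luteum and oocyte list means as covariates, and 4490 with array weights. The other settings, the block among them, left it within 1.5 times of 2986. Corpus luteum and oocyte list means themselves differ between the time points, and the cause of the other changes was not tested.

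Correlations of fold changes at 0 months under the stricter filter were 0.482 for DEHP 20 and DEHP 200, 0.42 for DEHP 20 and DiNP 20, 0.518 for DEHP 20 and DiNP 100, 0.324 for DEHP 200 and DiNP 20, and 0.45 for DEHP 200 and DiNP 100. At 3 months they were 0.534 for DEHP 20 and DEHP 200, 0.284 for DEHP 20 and DiNP 100, and 0.111 for DEHP 200 and DiNP 100. Quantile normalization at 3 months gave 0.286 for DEHP 20 and DiNP 20, 0.355 for DEHP 20 and DiNP 100, 0.338 for DEHP 200 and DiNP 20, 0.204 for DEHP 200 and DiNP 100, and 0.354 for DiNP 20 and DiNP 100. The cause was not tested. Simulated changes of 1.5-fold were recovered in 20 to 42% of genes, so that a count of 0 does not exclude them.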

Other observations

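The test of time over all groups was chosen only after the control time result was seen, whereas its random divisions were fixed before they were run. All 15 libraries of 3 months were compared with all 15 of 0 months, a contrast that also carries age and collection. Limma called 2986 genes, 1566 higher and 1420 lower at 3 months. The count was 135 with corpus luteum and oocyte list means as covariates and 1231 without the 4 libraries named above. Estrous stage at collection is not given, and corpus luteum and oocyte list means vary within groups. Of the oocyte list 24 of 24 members were lower, 21 of which fell past the threshold and 23 when adjusted over the list alone, with a median of -0.71 (adjusted p = 0.406 with an estimated correlation). Sohlh1, a transcription factor of early oocytes, fell by 1.47 ± 0.18 (adjusted p = 3.21e-05), Nobox by 0.87, the zona pellucida gene Zp2 by 0.81 and Gdf9 by 0.58. Granulosa cell genes were lower in 20 of 20 members, with 14 past the threshold and a median of -0.53 (adjusted p = 0.342 with an estimated correlation), among them Inhba (-1.07) and Amh (-0.57). Proliferation genes were lower in 30 of 30, with 23 past the threshold and a median of -0.36 (adjusted p = 0.417 with an estimated correlation). Aromatase (Cyp19a1) fell by 1.07, while Hsd3b1 rose by 0.67 and Akr1c18, the luteal enzyme that inactivates progesterone, by 3.43 ± 1.10 (adjusted p = 0.0318).

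Macrophage genes were higher at 3 months in 18 of 19 members, 16 of them past the threshold, with Csf1r at 0.66 and C1qa at 0.78. Interferon response genes were higher in 21 of 22, with 11 past the threshold and a median of 0.57. Cholesterol synthesis genes (median 0.46, 2 past), corpus luteum genes (0.58, 5 past), antioxidant genes (0.22, 6 past) and clock genes (0.18) were higher. Extracellular matrix genes were lower (-0.21), with 11 past the threshold, 1 of which, Mmp9, rose by 1.39. Smooth muscle genes were lower (-0.28), and not called without DEHP 20 replicate 1 of 0 months or DiNP 20 replicate 3 of 3 months (highest adjusted p = 0.0669). Unfolded protein response genes were higher (0.14), and not called without DEHP 200 replicate 2 or DiNP 20 replicate 3 of 3 months (highest adjusted p = 0.0573), while in controls alone they were lower (-0.24). None of the 12 lists held with an estimated correlation. In 9 genes all 15 libraries of each time point were separate, among them Smc1b (-1.07), Kdm1b (-0.31), Figla (-0.97) and Fndc5 (-0.82) on the lower side and Cbx7 (0.54), Skap2 (0.47), Gm7609 (2.78) and Cxcr6 (1.35) on the higher side. In 100 random divisions of the 30 libraries, 1 gave as many genes, the real one with 2986, and the highest other gave 1392, so that chance can be excluded for this count.

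The numbers of genes at an unadjusted p under 0.05 were set against all divisions of the same 6 libraries into 3 and 3, of which there are 10 with the real one counted, too few for a share under 0.05. At 0 months 3 of 10 divisions gave as many as DEHP 20 against control (real 350, highest other 429), 4 for DEHP 200 (740, 1646), 5 for DiNP 20 (307, 1030) and 7 for DiNP 100 (258, 601). At 3 months 7 gave as many for DEHP 20 (248, 1680), 6 for DEHP 200 (212, 2102), 9 for DiNP 20 (224, 1692) and 5 for DiNP 100 (1368, 4309). For DEHP 20 against DiNP 20 there were 7 at 0 months (302, 1044) and 5 at 3 months (427, 813). For DEHP 200 against DEHP 20 there were 8 at 0 months (582, 1762) and 10 at 3 months (141, 1083), and for DiNP 100 against DiNP 20 there were 10 at 0 months (86, 1084) and 4 at 3 months (1794, 3068). Control over time had 2 (1176, 1586), and its 11 list calls were reached in 2 of 10, with a highest other of 12. A division that calls several times the real count, as the highest for DEHP 200 at 3 months does with 2102 against 212 (median of the others 264), points to a structure of the samples, whose source was not tested.

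With 100 random regroupings chance could not be excluded for the time-by-treatment tests, where 57 gave as many genes for DEHP 20 (real 289, highest other 1431), 61 for DEHP 200 (375, 3131), 75 for DiNP 20 (219, 1988) and 69 for DiNP 100 (343, 3277). Nor could it for any treatment at 0 months, with 71 of 100 (325, 1242), or at 3 months, with 58 (588, 2587). At least as many list calls as the 53 in the 8 treated-versus-control comparisons came from 92 of 100 regroupings (median 64, highest 88). Chance cannot be excluded for that number. The highest correlation of fold changes at 0 months (0.69) was reached in 23 of 100 regroupings, and one as low as the lowest at 3 months (0.165) in 16 of 100.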
